A study of Arabidopsis thaliana with 6 samples.

How the data were processed

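Rosette leaf RNA of WT and ibm1-3 Arabidopsis was sequenced in 6 libraries: 1 per genotype in low light at 40 days and 2 per genotype after 48 hours of high light at 30 days. Groups were taken from the sample titles and characteristics. Libraries were made by Illumina and BGI protocols separately, per the labels' protocols, which do not say which sample had which. The series design and the labels name different RNA kits. Bowtie2 and TAIR10 are named in the submitters' processing notes. The counting program, strand setting and software versions are not given in the sources used here.

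The authors deposited 3 tables. The table of high light pair 1 holds estimated counts of fragments per gene and FPKM, per the file headers. The table of high light pair 2 holds a column headed expression whose deposited values behave as FPKM, with no counts. In both, a value of 0.01 stands where no fragment was counted. The authors' deposited log2 ratios equal the log2 ratios of these columns. The low light table holds a normalized signal per gene, deposited by the authors as read counts times a factor per library: 100% of nonzero values were whole multiples of a step within 0.01 steps, and the smallest was 15 steps, so genes under 15 reads are listed at 0 (5419 in WT, 5497 in ibm1-3). The authors' deposited p-values and q-values compare single libraries and were used only for the counts attributed to them. The tables had 22446, 23699 and 33602 rows, the last with values in 22878. In the table of pair 2, 1003 identifiers carry a transcript suffix and were left out. Both high light tables shared 21437 genes. Columns of pair 1 carry no replicate number and were taken as number 1 from the label that titles the table, and the description labels of some high light samples disagree with their titles on the number.

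Before the data were examined, edgeR was planned for high light if the tables held counts and limma on log2(value + 1) if they did not. Since the table of pair 2 has no counts, limma 3.58.1 (trend) in R 4.3.3 was used on log2(FPKM + 1), with genes of at least 1 FPKM in 2 libraries, and fold changes on that scale understate the change of low genes. The replicate number, which is also the table, was a block, because the tables were normalized separately. The labels tie each number to a table of its own. Deviations from the group means of samples with the same number correlated at 0.89 across genes. The fit has 1 residual degree of freedom and 6.17 prior degrees of freedom. Benjamini-Hochberg adjustment and a threshold of 0.05 were used. On simulated data from the real means, with 200 genes changed in each run, the test gave 10.2% false calls among its calls against a nominal 5%. Adjusted p-values near the threshold may therefore be optimistic. The real fit called 13087 of 17399 genes, far more than 200, so the false share of the simulation does not carry over to it.

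Gene lists (22 lists, 321 genes) were fixed before the data were examined, and 21 had enough members for camera with a preset correlation of 0.01, with an estimated correlation and fry as checks. Camera with an estimated correlation uses the 1 residual degree of freedom of the fit and could hardly pass. Its p-values, given beside the lists, therefore do not decide whether correlation between genes explains a result. They cover late anthocyanin genes, early phenylpropanoid and flavonoid genes, their regulators, light signalling, photoprotection, photosynthesis, heat shock, salicylate defence, jasmonate, glucosinolate, cold and drought, DNA methylation and silencing, reported IBM1 targets, flowering, senescence, clock, reference genes and 5 marker lists of other tissues. Named genes were chosen by a rule fixed beforehand. The rule takes IBM1 and the 10 highest and 10 lowest fold changes past the threshold with the same direction in both pairs and a mean of at least 5 FPKM. In low light it takes the 5 highest and 5 lowest log2 ratios with at least 100 reads. Over the 3 pairs it takes the 5 highest and 5 lowest by the smallest ratio. From each list it takes up to 4 members with the smallest p, and anthocyanin, reported target and salicylate genes whatever their p. PRR9, LUX, GI, 4CL1 and UGT78D1 fall outside the rule and were named after their values were seen, as were the genes that moved in opposite directions in low and high light.

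For low light, reads were scaled with edgeR 4.0.16 TMM factors and a prior count of 1. Genes with at least 50 reads over both libraries were kept, and a gene listed at 0 was set to 14 reads so that its ratio is a bound. Intervals are exact 95% binomial intervals (Clopper-Pearson). List medians were placed among 10000 random lists matched on mean expression. Members of the random lists were drawn independently, so the percentiles take no account of correlation between genes of a list. For the 3 pairs the planned minimum of 50 reads was replaced in the high light pairs by at least 1 FPKM in a library of each pair. The light comparison was planned as a test only if values could be compared between tables, and is descriptive. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Depth limits low genes: reads and fragments without molecular identifiers are not independent molecules, and intervals cover counting error only.

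Alternatives were other scalings, filters, pseudocounts and prior counts, a fit without the replicate block, all 6 libraries in a fit, and each high light library left out.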

Results

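Messenger RNA from rosette leaves of Arabidopsis thaliana (Columbia) was sequenced in 6 libraries. IBM1 encodes a histone demethylase of the jumonji family that keeps methylation marks of heterochromatin out of active genes, and ibm1-3 is a mutant allele of it. Under low light, 1 library came from wild type (WT) and 1 from ibm1-3 plants of 40 days. After 48 hours of high light, 2 libraries came from WT and 2 from ibm1-3 plants of 30 days, and each numbered high light pair of WT and ibm1-3 was deposited as a table of its own. High light pair 1 held 12121246 estimated fragments for WT and 12502408 for ibm1-3. The depth of pair 2 was not given, and its smallest values corresponded to about 21800000 fragments in each library. The low light pair held 15425082 reads for WT and 13099267 for ibm1-3. The 10 most abundant genes took 9.48% and 9.92% of the FPKM sum in the WT high light libraries against 4.56% and 4.35% in the ibm1-3 high light libraries.

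IBM1 (AT3G07610, chromosome 3, 2426069 to 2432913, forward strand, TAIR10 coordinates as deposited) was not consistently lower in the high light libraries labelled ibm1-3. Pair 1 had 564 estimated fragments of IBM1 in WT and 737 in ibm1-3, and pair 2 had 8.34 FPKM in WT and 7.46 FPKM in ibm1-3. The log2 fold change of 0.09 ± 0.13 (SE, n = 2 per genotype) did not pass the limma test (adjusted p = 0.526), and its sign turned with size factor scaling (-0.2). In the low light pair IBM1 had 643 reads in WT and 399 in ibm1-3, a log2 ratio of -0.71 with a 95% counting interval from -0.9 to -0.53 and no replicate. The transcript therefore did not check the genotype labels of the high light libraries, and every direction below is that of the libraries labelled ibm1-3 against those labelled WT.

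The first comparison asked how the genotypes differed after high light. Genes of flavonoid and anthocyanin synthesis were among the genes with the highest fold changes in the libraries labelled ibm1-3. DFR (AT5G42800; chromosome 5, 17164093 to 17166032), which makes leucoanthocyanidins, stood at 4.18 and 3.95 FPKM in WT and at 293.81 and 379.36 FPKM in ibm1-3, a log2 fold change of 6.05 ± 0.1 (SE, n = 2 per genotype; adjusted p = 1.95e-08). LDOX, the next enzyme of the pathway, rose by 5.58 ± 0.08 and chalcone synthase (TT4, AT5G13930; chromosome 5, 4488476 to 4490264) by 5.29 ± 0.06. Of 17399 genes tested with limma, 13087 passed a false discovery rate of 0.05, 8564 higher and 4523 lower in ibm1-3, and 4947 of the calls were at least 2-fold. With size factors, which moved the median log2 fold change of all genes from 0.251 to -0.041, the split was 6063 higher and 6733 lower. Without the replicate block 4622 genes passed. With a single genotype effect over the low and high light pairs, a fit chosen after the data were examined, limma called 0 genes (3624 at an unadjusted p under 0.05).

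The labels do not say that the numbered samples came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. The genotype ratios of the 2 high light pairs correlated at 0.97 across genes, which are not independent replicates. For genes of 100 to 300 counts the SD of the difference between the pairs was 0.25 on the log2 scale, against 0.177 from counting alone. The self-test for this comparison, over 17399 genes, recovered 91.2% of genes changed by a log2 of 1 and 94.4% of those changed by 2, and 10.2% of its calls were false. It changed 200 genes per run against 13087 called in the real fit, so these shares do not carry over. Its noise came from the spread between these libraries and covers no variation between plants. Adjusted p-values given below for a library left out come from limma fits of the other 3 libraries with no replicate block. These fits take in differences between the separately normalized tables, so a lost call does not show dependence on the library left out.

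Among 11 late anthocyanin genes, 9 rose, 1 fell and 1 did not pass (10 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 3.72. Besides DFR and LDOX, the glucosyltransferase UF3GT rose by 4.82 ± 0.08, the malonyltransferase 5MAT by 4.92 ± 0.11 and the glutathione transferase GSTF12 by 4.86 ± 0.08, while BGLU10 fell by 0.54 ± 0.06 (adjusted p = 0.128 without the replicate block). All 13 measured early phenylpropanoid and flavonoid genes rose, also adjusted over the list alone, with a median of 2.63. TT7 rose by 4.53 ± 0.11, CHIL by 4.32 ± 0.11 and FLS1 by 4.28 ± 0.11. Both lists passed camera (adjusted p = 0.00154 and 4.52e-05). With an estimated correlation, where camera has 1 residual degree of freedom and could hardly pass, p was 0.249 and 0.302. Of 14 regulators of this pathway 9 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.783). The activators MYB90 and TT8 rose by 3.92 ± 0.06 and 4.17 ± 0.11 and MYB75 by 1.26 ± 0.08. The repressors MYBL2, LBD39 and LBD37 fell by 4.03 ± 0.06, 3.09 ± 0.13 and 2.64 ± 0.08, while the repressors MYB4 and CPC rose by 0.86 ± 0.08 and 0.66 ± 0.14, CPC with an adjusted p of 0.0768 without the replicate block. TTG1, a partner of the activators, fell by 1.86 ± 0.07. With a library left out, BGLU10, MYB4 and CPC passed in 0 of the 4 fits (adjusted p from 0.279 to 0.533, 0.122 to 0.281 and 0.111 to 0.335), and MYB75 and TTG1 did not pass without WT replicate 1 (0.0921 and 0.0528), WT replicate 2 (0.161 and 0.113) or ibm1-3 replicate 1 (0.105 and 0.0582). Clock genes moved with these groups, CCA1 by -4.71 and TOC1 by 1.71.

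**Figure D1:**
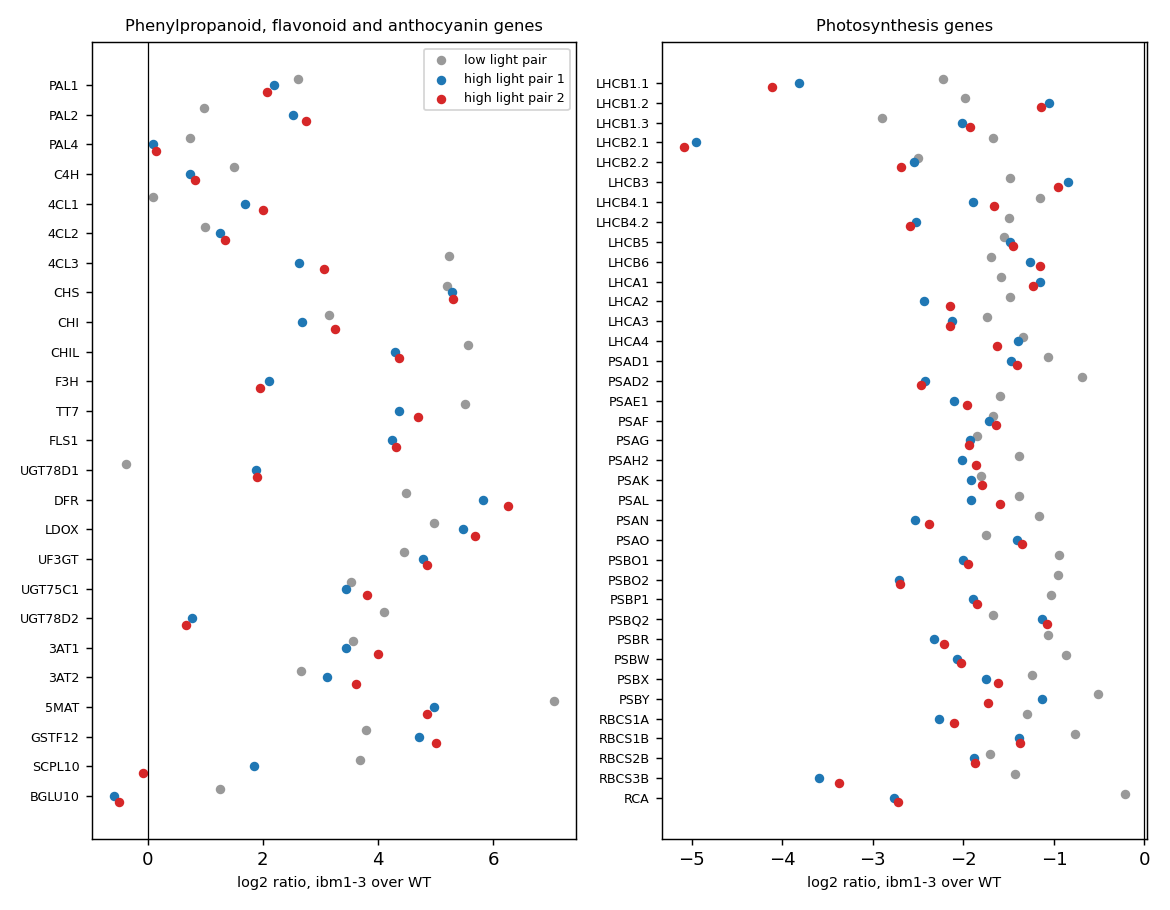
Each point is the log2 ratio of a gene in the library labelled ibm1-3 over the WT library of the same pair (x axis), for flavonoid and anthocyanin genes on the left and photosynthesis genes on the right; grey points are the low light pair, blue and red points the high light pairs. DFR lies at 4.48, 5.83 and 6.26 in the low light pair and high light pairs 1 and 2, and all 37 photosynthesis genes lie below 0 in each pair.

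All 37 nuclear photosynthesis genes fell in ibm1-3 after high light, also adjusted over the list alone and with size factors, with a median of -1.93. LHCB2.1, a light-harvesting protein of photosystem II, fell by 5.02 ± 0.06, LHCB1.1 by 3.96 ± 0.09, the photosystem II subunit PSBO2 by 2.7 ± 0.06 and the photosystem I subunit PSAD2 by 2.45 ± 0.06. The LHCB1, LHCB2 and RBCS copies are near-identical, so the split of reads among them is uncertain. The list passed camera (adjusted p = 6.02e-22; p = 0.116 with an estimated correlation). Of 20 photoprotection and antioxidant genes 13 fell and 7 rose, the same adjusted over the list alone, with a median of -1.36. The catalase CAT2 fell by 3.59 ± 0.06, zeaxanthin epoxidase (ZEP) by 2.94 ± 0.06 and PGR5 by 2.21 ± 0.06, while BAP1 rose by 2.82 ± 0.07. Of 20 light signalling genes 12 fell, 2 rose and 6 did not pass, the same adjusted over the list alone, with a median of -0.45. The photoreceptor gene CRY1 fell by 1.53 ± 0.06, HYH by 2.02 ± 0.1 and RUP2 by 1.72 ± 0.1, and PHYB rose by 1.3 ± 0.07. These 4 genes did not pass without WT replicate 1 (adjusted p = 0.0717, 0.0834, 0.0659 and 0.0861) or WT replicate 2 (0.0761, 0.0577, 0.0596 and 0.112), nor PHYB without ibm1-3 replicate 1 (0.0609) and PGR5 without WT replicate 2 (0.0642). Both lists passed camera (adjusted p = 0.00154 for each), with p = 0.391 and 0.217 with an estimated correlation. CCA1, a morning clock gene, fell by 4.71 on the log2 scale in the same libraries.

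Of 10 clock genes 6 rose, 3 fell and 1 did not pass, the same adjusted over the list alone, and the list did not pass camera (adjusted p = 0.812). The members that fell were morning genes, CCA1 by 4.71 ± 0.07, LHY by 4.12 ± 0.06 and PRR9 by 1.7 ± 0.16. Among the members that rose were the evening genes TOC1 by 1.71 ± 0.07, ELF4 by 1.74 ± 0.07, LUX by 2.02 ± 0.11 and GI by 2.19 ± 0.13. TOC1 and ELF4 did not pass without WT replicate 1 (adjusted p = 0.0556 and 0.0507), and TOC1, ELF4 and LUX did not pass without WT replicate 2 (0.0624, 0.0846 and 0.0673). RVE1, a morning-phased homologue of CCA1, was among the 10 genes with the lowest fold changes, at -5.57 ± 0.09. The list's median was 0.55 in pair 1 and 0.42 in pair 2 while its mean was -0.18. In the low light pair the log2 ratio of CCA1 was -0.03 and that of LHY 0.03, with TOC1 at -1.38 (95% counting interval -1.6 to -1.17), opposite to high light, ELF4 at 1.39 (0.92 to 1.92) and GI at 0.78 (0.58 to 0.99).

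**Figure D2:**
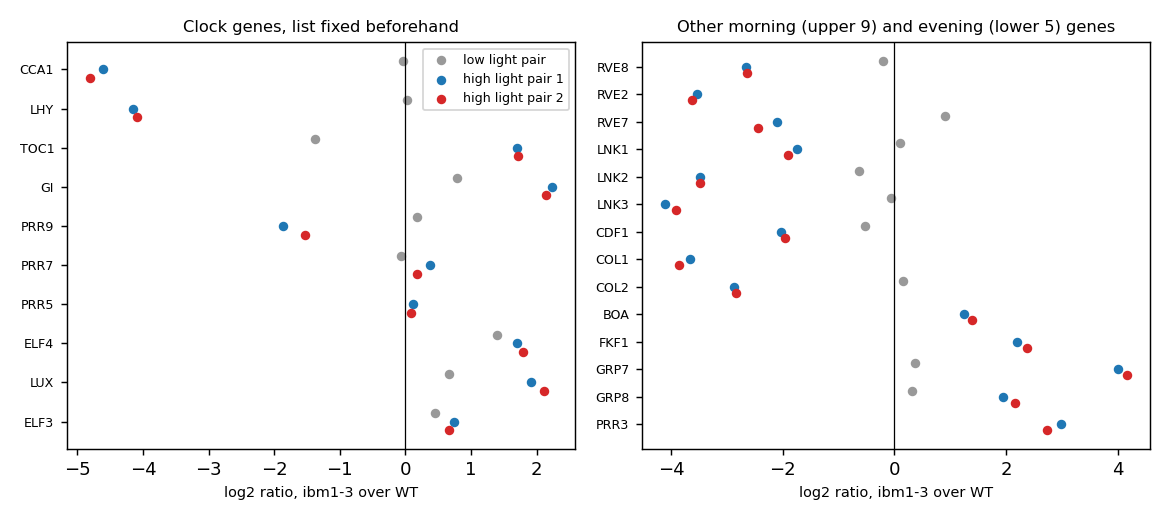
Each point is the log2 ratio of a gene in the library labelled ibm1-3 over the WT library of the same pair (x axis), for the clock list on the left and for other morning and evening genes, chosen after the left panel's values were seen, on the right; colours mark the low light pair (grey) and the high light pairs (blue and red). CCA1 lies at -4.61 and -4.81 in the high light pairs and at -0.03 in the low light pair.

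Stress and hormone genes also differed after high light. All 8 measured cold and drought genes rose, also adjusted over the list alone, with a median of 2.17 (camera adjusted p = 0.00154; p = 0.171 with an estimated correlation). RD29A rose by 3.74 ± 0.06, KIN1 by 3.26 ± 0.12, COR47 by 2.43 ± 0.06 and COR15A by 1.63 ± 0.06. Of 21 jasmonate genes 17 rose and 4 fell, the same adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.0355; p = 0.332 with an estimated correlation). The list did not pass camera without the replicate block (adjusted p = 0.131). JAZ5, LOX3 and OPR3 rose by 3.17 ± 0.06, 2.97 ± 0.06 and 2.43 ± 0.06, and the defensin gene PDF1.2 fell by 4.73 ± 0.06. Of 16 glucosinolate genes 15 rose and 1 did not pass, the same adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.00478; p = 0.409 with an estimated correlation), and 10 rose with size factors. The glucosinolate medians in pairs 1 and 2 lay at percentiles 95.18 and 95.72 of matched random lists. MYB51 rose by 2.24 ± 0.06, CYP79B2 by 1.94 ± 0.1 and CYP83B1 by 1.27 ± 0.06. CYP83B1 did not pass without the replicate block (adjusted p = 0.102) or in any of the 4 fits with a library left out (adjusted p from 0.0574 to 0.345). Of 26 salicylate and defence genes 17 rose, 5 fell and 4 did not pass, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.154). With size factors 14 rose and 9 fell. WRKY18, WRKY53 and WRKY46 rose by 3.15 ± 0.06, 3.01 ± 0.06 and 2.51 ± 0.06, PR1 rose by 2.29 ± 0.15, and ALD1 and FMO1 fell by 3.81 ± 0.09 and 2.46 ± 0.12. Without WT replicate 1, COR47 (adjusted p = 0.0522), COR15A (0.0587), CYP79B2 (0.0559) and PR1 (0.0594) did not pass, and without WT replicate 2, COR47 (0.0522), COR15A (0.11), CYP79B2 (0.0508), PR1 (0.0531) and OPR3 (0.0501) did not. COR15A also did not pass without ibm1-3 replicate 1 (0.0578). The fall of CCA1 by 4.71 accompanied these groups too.

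Of 11 senescence genes 8 fell, 2 rose and 1 did not pass, the same adjusted over the list alone, with a median of -1.16 (camera adjusted p = 0.00149; p = 0.16 with an estimated correlation). The dark-inducible gene SEN1 fell by 5.45 ± 0.08 and the transcription factor genes NAP and NAC092 by 3.78 ± 0.09 and 2.71 ± 0.07. Other genes with the lowest fold changes were BXL1 at -6.86 ± 0.14, AT3G15450 at -6.84 ± 0.1, AT4G27450 at -6.37 ± 0.14, AT1G49500 at -6.12 ± 0.19, BGAL4 at -5.49 ± 0.08, AT2G41250 at -5.48 ± 0.07 and the beta-amylase gene BMY3 at -5.43 ± 0.07. PDF1.2b lay at -5.88 ± 0.26, where reads shared with its near-identical copies leave the split uncertain. The other genes with the highest fold changes were PHI-1 at 5.95 ± 0.08, AT4G27654 at 5.92 ± 0.12, CYP707A3, an enzyme of abscisic acid breakdown, at 5.78 ± 0.08, FBS1 at 5.7 ± 0.07, AT2G35290 at 5.53 ± 0.11, the glucose 6-phosphate carrier GPT2 at 5.51 ± 0.1, CML38 at 5.45 ± 0.06 and AHP4 at 5.35 ± 0.18. CCA1 and LHY fell in the same libraries.

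Of 27 DNA methylation and silencing genes 19 rose, 1 fell and 7 did not pass, the same adjusted over the list alone, with a median of 0.55, and the list did not pass camera (adjusted p = 0.082). It passed with size factors (adjusted p = 0.0465) and without the replicate block (adjusted p = 0.0184), and p was 0.259 with an estimated correlation. The silencing list also passed fry (adjusted p = 0.0104), which tests each list alone. Its medians in high light pairs 1 and 2 lay at percentiles 85.42 and 82.77 of matched random lists. AGO4, CLSY1, CMT2 and NRPD2 rose by 1.88 ± 0.14, 1.75 ± 0.14, 1.73 ± 0.13 and 1.64 ± 0.13. With size factors 14 rose and 4 fell. CLSY1, CMT2 and NRPD2 did not pass without WT replicate 2 (adjusted p = 0.0551, 0.0806 and 0.069), nor NRPD2 without WT replicate 1 (0.0502). Of genes reported elsewhere as affected by loss of IBM1, ER rose by 0.71 ± 0.16, DCL3 by 0.55 ± 0.15 and BNS by 0.31 ± 0.12, and with size factors 1 of these 3 passed (camera adjusted p = 0.577). The list of these 3 genes passed fry (adjusted p = 0.0044). Without the replicate block 0 of the 3 passed limma (adjusted p = 0.11, 0.0599 and 0.288), and 0 passed in any fit with a library left out. Of 9 flowering genes 6 rose and 3 fell (adjusted p = 0.81), SPL4 by 1.3 ± 0.08, TSF by 1.56 ± 0.13, FT by -0.87 ± 0.07 and SOC1 by -0.78 ± 0.06. Of 7 heat shock genes 2 rose, 4 fell and 1 did not pass (adjusted p = 0.406), with DREB2A at 1.98 ± 0.08 and HSP90.1 at -1.55 ± 0.07. Of 8 reference genes 3 rose, 3 fell and 2 did not pass (adjusted p = 0.592). UBQ10 stood at -1.4 ± 0.07 and EF1A at 0.9 ± 0.06, and with size factors 2 rose and 5 fell. Without the replicate block SPL4 (adjusted p = 0.107), HSP90.1 (0.0961) and EF1A (0.137) did not pass. With a library left out, FT, SOC1, UBQ10 and EF1A passed in 0 of the 4 fits (adjusted p from 0.134 to 0.232, 0.202 to 0.272, 0.145 to 0.194 and 0.143 to 0.49). SPL4, TSF, DREB2A and HSP90.1 did not pass without WT replicate 1 (0.0987, 0.104, 0.0512 and 0.253) or WT replicate 2 (0.306, 0.0551, 0.0948 and 0.0754), nor SPL4 without ibm1-3 replicate 1 (0.237) and HSP90.1 without ibm1-3 replicate 2 (0.173). Each of these counts was the same adjusted over the list alone. Marker lists of other tissues did not pass camera: the adjusted p was 0.577 for guard cells, 0.577 for phloem and vessels, 0.81 for epidermis and trichomes and 0.767 for root, and floral markers were too few to test. Single markers did pass limma. Of 5 epidermis and trichome markers 3 rose and 2 fell, with ATML1 at 1.06 ± 0.11, FDH at 0.97 ± 0.07, KCS6 at 0.87 ± 0.06 and CER1 at -2.02 ± 0.15. Of 7 phloem and vessel markers 4 rose, XCP2 by 1.29 ± 0.1, and of 4 guard cell markers 1 rose and 2 fell. With size factors 2 phloem and vessel markers rose and 2 fell, and 0 guard cell markers rose and 2 fell. Of 2 measured root markers the phosphate transporter gene PHT1.4 rose by 3.77 ± 0.11, and the root list passed fry (adjusted p = 0.00447). KCS6 did not pass without the replicate block (adjusted p = 0.312), and ATML1, FDH and KCS6 passed in 0 of the 4 fits with a library left out (adjusted p from 0.0806 to 0.183, 0.0822 to 0.22 and 0.107 to 0.732), XCP2 only in that without ibm1-3 replicate 2 (0.0404; 0.0854 to 0.146 in the others).

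The second comparison asked how the genotypes differed in low light, where 1 library per genotype gave no replicate check and no test, and intervals cover counting error only. Percentiles among matched random lists treat genes as independent draws and measure no spread between plants. All 11 late anthocyanin genes were at least 2-fold higher in the library labelled ibm1-3, with a median log2 ratio of 3.8 at percentile 100 of matched random lists. Of 12 early phenylpropanoid and flavonoid genes with enough reads, 7 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 2.05 at percentile 100. 5MAT had a log2 ratio of 7.06 (95% interval 6.48 to 7.9), CHIL of 5.57 (5.28 to 5.91), TT7 of 5.51 (5.29 to 5.75) and 4CL3 of 5.23 (4.69 to 5.98). DXPS1 was listed at 0 in WT and had 628 reads in ibm1-3, at least 5.37 higher on the log2 scale. Of the early genes, 4CL1 stood at 0.1 and UGT78D1 at -0.38 (-0.56 to -0.21), and FLS1 had 19 reads in WT and was listed at 0 in ibm1-3. F3H was listed at 0 in both libraries, although its means after high light were 14.3 FPKM in WT and 62.2 FPKM in ibm1-3. Why it was listed at 0 was not tested. MYBL2, which fell after high light, had a low light log2 ratio of 1.35.

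Photosynthesis genes were lower, 30 of 37 by at least 2-fold, with a median of -1.48 at percentile 0. Of 20 jasmonate genes 14 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.44 at percentile 0. Salicylate and defence genes went both ways, 9 of 25 at least 2-fold lower and 6 at least 2-fold higher, with a median of -0.82 at percentile 0. Among the higher ones, PR1 stood at 2.39, WRKY38 at 3.82 and NIMIN1 at 2.54. Heat shock genes had a median of -1.05 at percentile 0.5. PDF1.2c and PDF1.2 had log2 ratios of -7.79 and -7.25, and PDF1.2b, listed at 0 in ibm1-3, lay at least 5.68 lower, with the reads of these copies hard to tell apart. The pseudogene AT4G16870 had a log2 ratio of -5.8 and the lectin gene AT3G15356 of -5.29. Senescence genes had a median of 0.67 at percentile 100. Glucosinolate genes went both ways, 6 of 15 at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.65 at percentile 100. MYB51, CYP83B1 and CYP79B2, whose fold changes were positive after high light, stood at -2.37, -1.79 and -1.2. Among 16509 genes, 2543 were at least 2-fold apart, 938 higher and 1605 lower. Scaling by total reads, which moved the median of all genes from 0.011 to 0.27, gave 1582 higher and 1149 lower. The authors' deposited table lists 1531 genes with a q below 0.005, 698 of them higher in ibm1-3 and 833 lower, from a test that compares these libraries and not the genotypes.

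The third comparison asked which differences recurred in the low light pair and both high light pairs, which share no library. Of 15786 genes, 399 were at least 2-fold apart in the same direction in all 3 pairs, 228 higher and 171 lower in ibm1-3. If low light calls fell independently of the genes called in both high light pairs, 256.3 would be expected. The high light pairs, whose ratios correlated at 0.97, entered as a unit, also in the expected counts below. These counts therefore compare low light with high light and not 3 independent pairs. The genes with the highest smallest ratio were TT4, LDOX, 5MAT, DFR and UF3GT, with low light log2 ratios of 5.2, 4.97, 7.06, 4.48 and 4.46. The lowest were PDF1.2b, PDF1.2, PDF1.2c and PDF1.3, and BBX30, a B-box gene, at -3.08 in low light and -3.4 ± 0.14 after high light. Another 660 genes were lower in low light and higher after high light (241.1 expected), and 89 were higher in low light and lower after high light (68 expected). Low light ratios were scaled with TMM factors and high light ratios carried no size factors, so the splits by direction depend on unlike scaling. With size factors the high light calls of at least 2-fold were 2229 higher and 2420 lower, against 3298 and 1649 without. The counts over the 3 pairs were not repeated with size factors. With low light scaled by total reads, 339 genes were higher and 131 lower in all 3 pairs, 514 were lower in low light and higher after high light (172.1 expected), and 149 were higher in low light and lower after high light (117.7 expected). Across genes the low light log2 ratio correlated with those of the high light pairs at -0.07 and -0.08.

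The fourth comparison set high light against low light and is descriptive, because the tables were normalized separately and the plants also differed in age. In WT the clock list stood at a median log2 ratio of 1.54 relative to all genes, the light signalling list at 1.18, the photoprotection list at 1.18 and the cold and drought list at 1.25. In ibm1-3 the corresponding medians were 1.06, -0.16, -0.37 and 3.94. The late anthocyanin list lay at -1.04 in WT and -1.38 in ibm1-3, and the photosynthesis list at -0.03 and -1.01. Light, age, table and library preparation cannot be separated in these values.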

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

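Tests on the clock in low light, on scaling, on the agreement of the pairs and on IBM1 were chosen after their results were seen; the tests on other morning and evening genes and on dark-induced genes used lists chosen after CCA1, LHY, RVE1, the dark-inducible gene SEN1 and the other genes with the lowest fold changes had been seen, with the lists' own values not yet seen. Differences between low and high light below were not tested, since low light has 1 library per genotype; they are named because the low light pair moved one way and both high light pairs the other, by at least 0.3 on the log2 scale for list medians and 1 for genes.

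Opposite list medians in low light were 0.37 for light signalling, -0.82 for salicylate and defence, -1.44 for jasmonate, -0.68 for cold and drought, -0.81 for reported IBM1 targets, 0.67 for senescence and -0.93 for epidermis and trichome markers. Low light was scaled with TMM factors, while the high light pairs carried no size factors. With size factors the medians of these lists in the high light fit were, in that order, -0.76, 0.31, 0.45, 1.87, 0.39, -1.48 and 0.55. Some rest on few genes that differ between pairs. Low light and high light pairs 1 and 2 had 5, 4 and 3 reported targets, 4, 8 and 8 cold and drought genes and 4, 5 and 4 epidermis markers. The high light medians of the reported targets lay at percentiles 53.01 and 57.96 of matched random lists, so they did not stand apart from other genes. Higher in low light and lower after high light were AT1G09500 (low light log2 ratio of at least 4.89), NIT2 (3.17), UGT74E2 (2.57), KTI1 (2.26) and AIG1 (2.09), among 89 such genes; after high light KTI1 did not pass without WT replicate 2 (adjusted p = 0.0605) nor AIG1 without WT replicate 1 (0.0576). Lower in low light and higher after high light were PHI-1 (-4.09, a bound), SRO5 (-4.07), DDF1 (-4.68, a bound), AT5G28610 (-4.52, a bound), AT3G02840 (-3.71), AT4G27654 (-2.96), CYP707A3 (-3.34), FBS1 (-2.33), AT2G35290 (-3.48) and CML38 (-2.47), among 660 such genes.

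Clock genes differed between the genotypes in high light. Scaling of the libraries is argued against, since a factor per library moves all genes alike, while the medians of other morning genes (-2.85) and other evening genes (2.28) had opposite signs and lay 5.13 apart. A candidate explanation is that the high light libraries of the genotypes differ in clock phase, for example through the hour of harvest, which the labels do not give: over 9 other morning genes and 5 other evening genes the difference was 5.07 in the pair where it was smaller. A dark or starved state of the WT high light libraries also remains open, as 13 dark-induced and starvation genes had a median of -1.34 in the pair where it was nearer 0, although 2 of them rose. A ratio between genotypes does not show whether the WT or the ibm1-3 libraries moved. In the low light pair 10 of these genes had a median of -0.02. Whether the genotype itself shifts the clock cannot be told apart, because low light, where CCA1 stood at -0.03, TOC1 at -1.38 (opposite to high light), ELF4 at 1.39 and GI at 0.78, has 1 pair of libraries, and a difference in phase between the high light libraries is not excluded.

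The 2 high light pairs gave nearly the same ratios. The SD of their difference was 3.61 times the counting SD for genes above 3000 counts, more than counting alone would give for a single library sequenced again. The counts of pair 2 were rebuilt from FPKM and an estimated depth, so part of the excess may come from processing. Repeated deposit of a single library, processed in different ways, is therefore not excluded. A candidate explanation is that the pairs are 2 library preparations of the same RNA: genes of lists that change within hours differed between the pairs no more than other genes (percentile 31.4 among 2000 matched random lists). The same value would be seen in pooled plants harvested together, which was not tested. If it were the same RNA, the high light p-values would measure preparation and sequencing only.

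IBM1 was not consistently lower in the high light libraries labelled ibm1-3, with log2 ratios of 0.33 in pair 1 and -0.14 in pair 2 (fold change of -0.2 with size factors). Labels swapped within a single high light pair are argued against by the correlation of 0.97 between the pairs' ratios. Whether the insertion leaves transcript that gene-level values count cannot be told apart from wrong labels in both pairs, since the fold change of 0.09 covers the whole gene and places no reads within it. In the low light pair, where IBM1 was lower (-0.71), all 37 photosynthesis genes had the same direction as in both high light pairs. The late anthocyanin list had a median of 3.8 against 3.44 and 4.0. Both lists were fixed before the data were examined, and both run with the labels as given. The reported IBM1 targets, also a fixed list, had opposite signs, with a median of -0.81 over 5 genes in low light. In the high light pairs it was 0.47 over 4 genes and 0.56 over 3. The other lists with opposite medians are named above. Across all genes the low light ratios correlated with those of the high light pairs at -0.07 and -0.08. In all pairs 399 genes were at least 2-fold apart in the same direction (256.3 expected), against 660 and 89 in opposite directions (241.1 and 68 expected). These counts set scaled low light ratios beside high light ratios without size factors. A single low light pair excludes nothing, so wrong labels in both high light pairs stay open.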

How the results depend on the processing

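The fit with a single genotype effect over all pairs and the filter at a mean of 5 FPKM were chosen after the data were examined. High light calls stayed within 1.5 times of 13087 with size factors, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, organelle genes left out and low light as a further block. With size factors 10602 of the 12978 calls still tested passed again, in whichever direction, and 545 of the 12978 had the opposite sign. They moved to 4622 without the replicate block, 4947 at 2-fold, 0 with 1 genotype effect over 3 pairs (limma; 3624 at an unadjusted p under 0.05), and between 1242 (without WT replicate 2) and 3395 (without ibm1-3 replicate 1) with a library left out, which gave 1380 without WT replicate 1 and 3384 without ibm1-3 replicate 2. The fits without a library have no replicate block, so they set separately normalized tables side by side, and the lone sample is assumed to vary like the other group. The low light count stayed within 1.5 times, and the count in all 3 pairs moved to 1237 at 1.5-fold. With total reads in place of TMM the 89 genes higher in low light and lower after high light became 149. Of 9 lists that passed camera, 0 passed with an estimated correlation and 15 lists passed fry, which tests each list alone. Lists that passed fry but not camera were the regulators (fry adjusted p = 0.0463), clock (0.0121), silencing (0.0104), reported targets (0.0044), salicylate and defence (0.0413) and root (0.00447). With 1 residual degree of freedom the check with an estimated correlation could hardly pass, so its outcome decides nothing. Estimated correlations were 0.44 for early phenylpropanoid genes, 0.35 for glucosinolate, 0.33 for photoprotection, 0.13 for late anthocyanin and 0.1 for photosynthesis. They were 0.07 for jasmonate, 0.04 for light signalling, -0.02 for senescence and -0.07 for cold and drought, against the preset 0.01. Where the estimate exceeds the preset, camera with the preset may be optimistic. The senescence list had a camera p of 0.16 with its estimated correlation. Without the block the jasmonate list lost its call (0.131) and the silencing list gained one (0.0184), as it did with size factors (0.0465). The direction of the clock list turned under fry (0.0121) and without the block (0.933), that of epidermis markers without the block (0.973) and that of reference genes under fry (0.905). IBM1 was -0.2 with size factors and between -0.48 and 0.66 with a library left out (-0.24 without WT replicate 2). SCPL10 (-0.17) and SPL9 (-0.12) turned without WT replicate 1. Of 131 named or listed genes, 53 lost their call in some fit with a library left out and 17 without the block. The fits with a library left out also drop the block, so a lost call does not show dependence on that library. For genes of 300 to 1000 counts the SD of WT values between the high light tables was 0.52. The SD of the difference between the paired ratios was 0.164. How many calls were lost for this reason was not tested. DESeq2, the mean count filter and the tests of light were not run, because a table has no counts and tables were normalized separately. Depth limits genes listed at 0.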

Other observations

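Among genes called at least 2-fold in high light, terms of the annotation in the authors' table were tested with a one-sided hypergeometric test, over 292 terms of 20 to 500 genes in each direction, against the 12168 annotated genes of the high light fit. Among 1211 lower genes, 56 of 115 genes of the photosynthetic light reaction (11.4 expected; adjusted p = 3.09e-24) and 85 of 223 of ribosome biogenesis (22.2 expected; adjusted p = 2.48e-27) were found. Among 2415 higher genes, 220 of 462 genes of the response to organonitrogen compounds (91.7 expected; adjusted p = 2.1e-40), 128 of 319 of RNA modification (63.3 expected; adjusted p = 2.65e-15), 50 of 95 of ribonucleoprotein complex biogenesis (18.9 expected; adjusted p = 5e-11) and 61 of 131 of cell wall organization (26 expected; adjusted p = 1.59e-10) were found. The terms named were chosen after their values were seen. Because the hypergeometric test treats genes as independent draws, it takes no account of correlation between genes of a term. Its calls came from 2 libraries per genotype, which the labels do not say came from separate plants. These p-values therefore describe overlap with the calls, and measure neither spread between plants nor an effect of the genotype. Clock genes differed between the same libraries, so the terms are not separated from the clock difference. Over all genes the calls of at least 2-fold were 3298 higher and 1649 lower. With size factors they were 2229 higher and 2420 lower, and terms were not tested on those calls.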
